A study of Homo sapiens with 7 samples.

How the data were processed

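Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in LS174T, an established human colorectal carcinoma cell line. Per the labels, there were 7 libraries in 5 groups. The transcription factor GATA6 was precipitated in 3 libraries, 1 library was sequenced from input DNA without an antibody, and 1 library each was made for the histone modifications H3K27ac, H3K4me3 and H3K4me1. Per the labels' protocols, cells grown with 10% serum were cross-linked with 1% formaldehyde for 15 min, fragments of 50 to 250 bp were selected, and libraries were amplified with 12 cycles of PCR. The 3 GATA6 libraries carried separate numbers, but nothing in the labels said whether they came from separate cultures.

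One processed file was used, a list of GATA6 peaks. The histone modification and input libraries were not analysed here. Per the submitters' processing notes, the tools were CASAVA 1.8 and BWA 0.5.9-r16 for the GATA6 and input libraries, and the build was hg19. The peak caller, its settings and the control it used are not given in the sources used here, nor is it stated whether the 3 GATA6 libraries were pooled before peaks were called. The list held no value per library, so no value below has a spread between replicates, and the depth of each library is unknown.

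Per the file headers, each peak had a start, an end, a length, a summit, and 4 scores. The pileup, a coverage signal that is called the height here, was deposited as whole fragments at the summit and was not scaled to library size. The fold enrichment was deposited as a linear ratio of the height over a local background. The p-value and the q-value were deposited as −log10 values by the authors. Positions were counted from 1, since the deposited length equalled the end minus the start plus 1 in all 7568 peaks. These scores are the authors' own, and they were used to describe, rank and filter peaks within this list.

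The local background at each peak was computed as its height divided by its fold. The deposited −log10 p was recomputed as the Poisson probability of more fragments than the height at that background, and the largest difference from the deposited value was 0.0159. The background had a floor of 0.489 fragments. Above it, the values were multiples of 0.998 fragments (1 control fragment within the 175 bp of the narrowest peak), or of the background that 1 control fragment gives in 1 kb or 10 kb, with a tolerance of 0.0005 of the value beside the rounding of the fold. All 7568 values (100%) lay on the floor or on such a step, against 26.7% of values drawn evenly in a simulation. The background was therefore read as a local control level, although no source names the control.

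Peaks on chromosomes 1 to 22 and X entered the comparisons, and the 6 peaks elsewhere are given separately. Since no hg19 sequence or annotation was used here, several tests fixed before the data were examined were not run. These were the promoter share, the GATA motif and the other motifs, the gene lists, and the naming of genes, including GATA6, LGR5 and BMP4. Peaks are therefore given by position only. Of the rule for named items, the part that could be applied took the 10 peaks with the best score, ranked by −log10 p. Clusters and dense regions given below were chosen by their size after their values were seen.

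For the same reason, the length of each chromosome was replaced by the span between its first and last summit, a choice made after the data were seen. Peaks per chromosome were compared with an even spread over these spans by exact binomial tests, two-sided, with Benjamini-Hochberg adjustment over 23 chromosomes. The standard error of peaks per Mb was taken over windows of 5 Mb. Chromosome X was compared with the other chromosomes by an exact test in which each chromosome in turn was set against the mean of the others. Both sides of the largest peak-free interval of chromosome 1 were compared by an exact test over all 809 rotations of its ordered peaks, which keeps neighbouring values together. Clusters were 4 or more peaks whose neighbouring summits lay within 10 kb, and they were compared with 1000 shuffles that drew positions evenly between the first and last summit of each chromosome. Peaks with and without a neighbour within 10 kb were compared by two-sided permutation tests of the difference in medians, with 100000 permutations. Intervals of a height are exact Poisson intervals at 95%. They cover counting error only, since fragments without molecular identifiers are not independent molecules.

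The cluster count was tested on simulated data before use. All 30 clusters planted among 7562 evenly drawn positions were gained, and 0 of 40 even draws gave p under 0.05. Both checks were easy to pass. The planted peaks were spaced within the linking distance, and even positions held 0.153 clusters on average, so such a p was rarely reachable. For the exact rotation test, a series of 800 values with a step of 0.5 standard deviations gave p = 0.0388.

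Alternatives fixed before the data were examined were the better-scoring part of the list, at or above the median −log10 p, merged overlapping peaks, linking distances of 5 and 20 kb, and clusters of at least 3 or 6 peaks. Others were chosen after the data were seen. These were a q of at most 0.01, summits joined within 1 kb or peaks joined within 10 kb, spans without the largest peak-free interval, occupied 1 Mb bins, shuffles within 1 Mb bins, peaks without a neighbour, and ranking by height or fold. For some results the better-scoring part was also applied only afterwards. These were the height and background of chromosome X, the sides of chromosome 1, the background of chromosome 15 and the heights of peaks with a neighbour. For the last, the linking distances were added afterwards too. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.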

Results

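The study mapped where GATA6, a zinc-finger transcription factor of endoderm-derived tissues, bound the genome of LS174T colorectal carcinoma cells. Its data comprised 3 GATA6 ChIP-seq libraries, 1 input library and 3 libraries of histone modifications. The GATA6 peak list was the file analysed here, so the comparisons that follow are between regions of one list. Positions are those of hg19. Peaks are not replicates, and p-values measure only the placement or spread of peaks within this list.

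GATA6 peaks were narrow and mostly well above their local background. The list held 7568 peaks that together covered 2085703 bp. The median width was 251 bp, with an interquartile range of 202 to 320 bp, and 684 peaks (9.04%) had the smallest width of 175 bp. The median height was 16 fragments, with an interquartile range of 12 to 23 and a full range of 6 to 130. The median fold over the local background was 14.03, and 5791 peaks (76.5%) reached a fold of at least 10. Only 110 peaks had a fold under 5, while 126 reached 50 and 6 reached 100. The authors' −log10 q ranged from 1.37 to 161.42 with a median of 9.24, and 7516 peaks (99.3%) had a q of at most 0.01. These scores measure height against the same background, and a peak list holds only regions that score well. The folds and q-values therefore describe the list and do not test GATA6 binding.

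Counting error limits single heights. A height of 16 has a 95% Poisson interval of 9.15 to 26.0, and the smallest height of 6 has one of 2.20 to 13.1. No peaks overlapped, and the median summit lay at 48.7% of the peak's width. Across the 7562 peaks on chromosomes 1 to 22 and X, wider peaks were also higher, with a Spearman rho of 0.66. Height rose with the local background (rho = 0.48), whereas the fold fell with it (rho = −0.58). These relations are across peaks, which are not independent, and the fold contains the background by construction. The same −log10 p also needs a greater height where the background is higher. Differences in height and in background below are therefore not separate results.

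The most significant GATA6 peak lay on chromosome 6 from 109225053 to 109225452. Its height was 112 fragments (95% Poisson interval 92.2 to 135) and its fold was 80.19, with a −log10 p of 168.55. The next was the widest peak of the list, 1223 bp on chromosome 3 from 190039862 to 190041084. It was also the highest, with 130 fragments (109 to 154) at a fold of 43.44. The intervals of these heights overlapped, so their order by height was not resolved.

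Peaks on chromosome 16 from 85568983 to 85569445 and on chromosome 20 from 62661892 to 62662321 had equal scores, each with a height of 83 (66.1 to 103) and a fold of 118.85. The chromosome 9 peak from 2771116 to 2771548 reached a height of 76 at a fold of 108.83. On chromosome 7, the peak from 73027074 to 73027409 had the largest fold of the list, 138.96, at a height of 68 (52.8 to 86.2). The chromosome 10 peak from 45241296 to 45241736 had a height of 70 and a fold of 114.56, and a further chromosome 20 peak from 16710453 to 16710793 had a height of 80 and a fold of 80.19. Chromosome 1 held the remaining pair, from 232817988 to 232818439 (height 96, fold 48.11) and from 239376090 to 239376647 (height 97, fold 39.69). Of these 10 peaks, 4 were also among the 10 highest and 5 among the 10 with the largest fold, and 0 were in both.

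**Figure D1:**
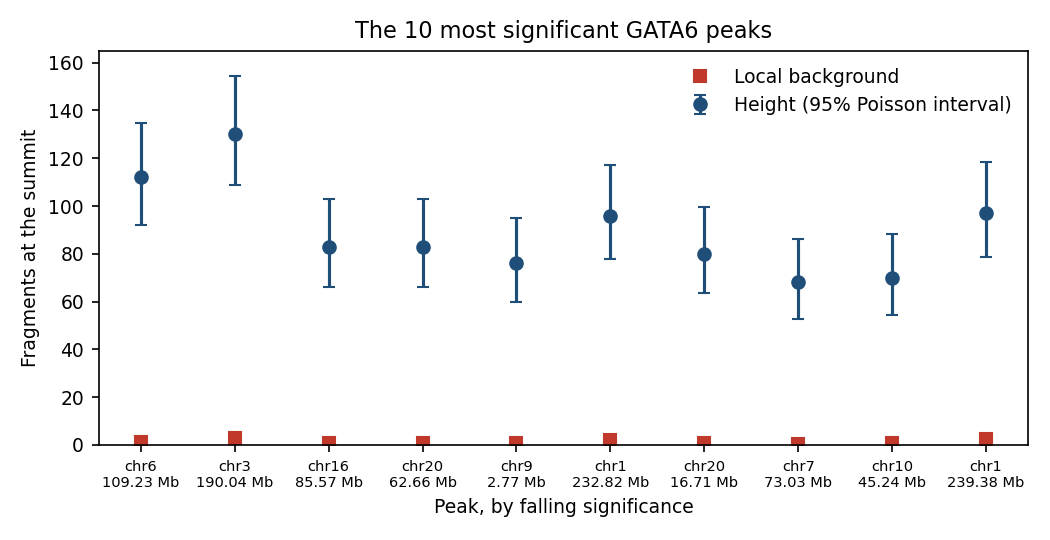
Fragments at the summit (y axis) of the 10 most significant GATA6 peaks (x axis, chromosome and summit position in Mb, hg19). Circles are heights with 95% Poisson intervals and squares are the local background; heights lie between 68 and 130, while the highest background is 2.99.

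GATA6 peaks were sparsest on chromosome X. It carried 168 peaks, or 1.11 ± 0.169 per Mb (SE over 30 windows of 5 Mb), against 2.69 per Mb over the autosomes together. Single autosomes ranged from 1.95 per Mb on chromosome 16 to 3.34 per Mb on chromosome 17. Chromosomes 1, 12 and 17 held more peaks than an even spread over the spans, at 1.26, 1.23 and 1.28 times the expected number. Chromosomes 5, 9, 13, 16, 18 and X held fewer, from 0.872 times the expected number on chromosome 5 down to 0.427 times on chromosome X.

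These 9 of 23 chromosomes passed exact binomial tests with Benjamini-Hochberg adjustment, with adjusted p = 1.2e-37 for chromosome X, 3.9e-10 for chromosome 1 and 0.00016 for chromosome 12. Neighbouring peaks were not independent, since they gathered locally, so these p-values are too small. With peaks joined within 10 kb, 8 chromosomes were off the even spread, and in the better-scoring part of the list 6. Spans without their largest peak-free interval gave 9, but not the same ones: chromosome 9, whose interval was 32.7 Mb long, went to 1.03 times the expected number (exact binomial test, adjusted p = 0.708), and chromosome 15 was called, at 1.19 times (adjusted p = 0.0193). Over the 1 Mb bins that held a peak, a measure that shrinks differences in density by construction, 2 were off it, chromosome 1 above and chromosome X below.

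The peaks of chromosome X were also lower. Their median height was 12 fragments against 16 on the autosomes, where single chromosomes had medians from 14 to 18. Their mean local background was 0.825 ± 0.0384 fragments (SE over 168 peaks), against 1.37 ± 0.00974 over 7394 autosomal peaks. A lower background lets lower peaks reach the same −log10 p, so the lower heights are not a trait separate from the background. On chromosome X, 33.3% of peaks had the floor background, against 5.59% on the autosomes together and 18.1% on chromosome 19, the highest single autosome. The median fold went the other way, at 16.7 on chromosome X and 14.03 on the autosomes, but chromosome 19 came close at 16.35. Among the 23 chromosomes, chromosome X ranked lowest in peaks per Mb, median height and mean background and highest in median fold. Chromosome X was singled out after its values were seen, so the exact p of 0.0435 for each of these, the smallest that 23 chromosomes allow, only restates its extreme rank. Without peaks that had a neighbour within 10 kb, its median height differed from the autosomes by −2.5 fragments in place of −4. Its mean background then differed by −0.494 fragments in place of −0.546. The exact p of that background was 0.087, since chromosome 15 took the place farthest from the others.

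**Figure D2:**
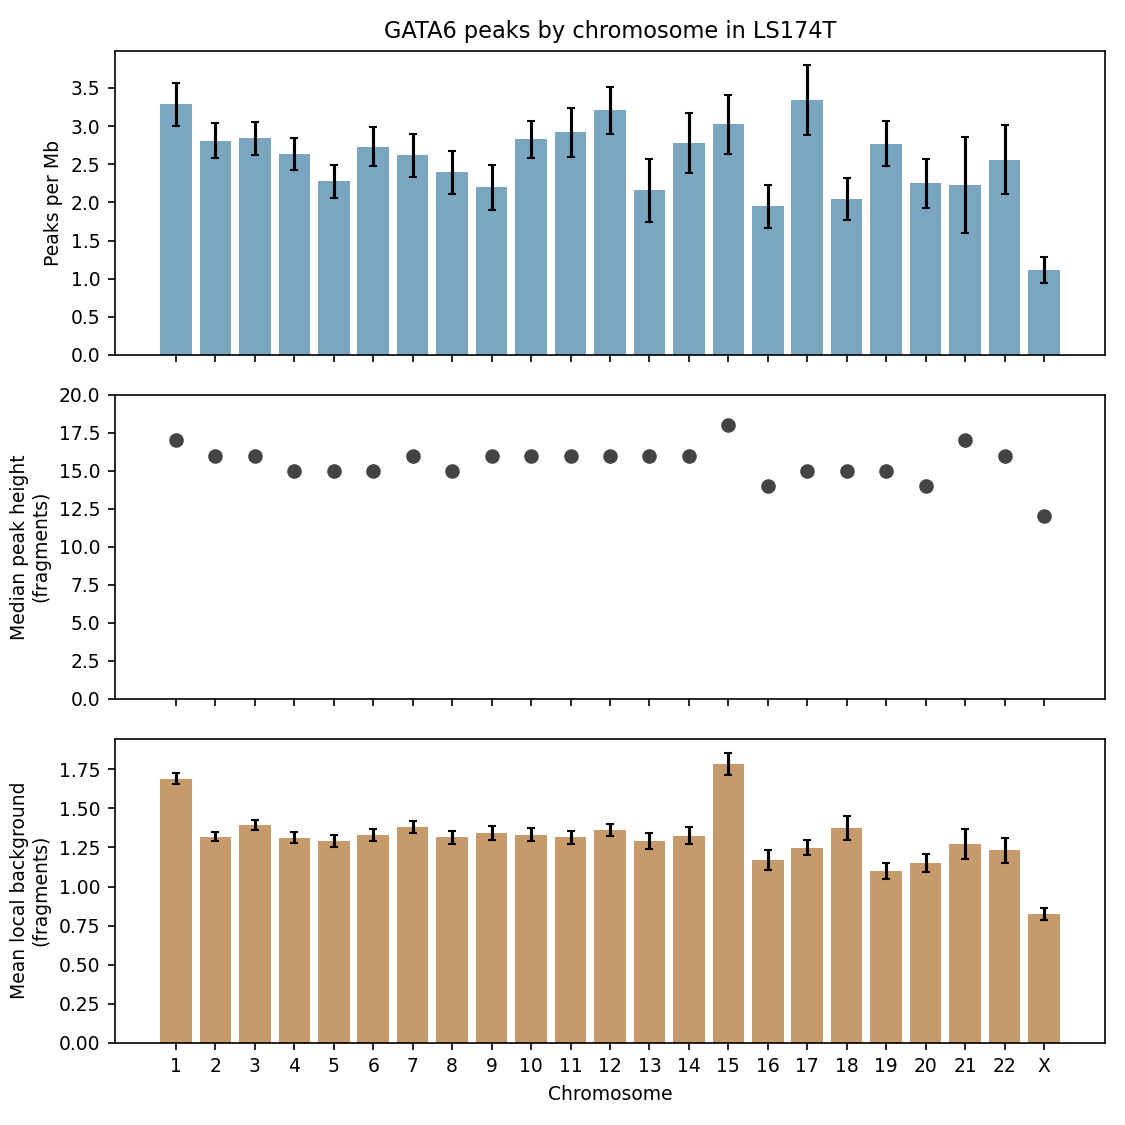
GATA6 peaks per Mb of span (top, bars with SE over 5 Mb windows), median peak height in fragments (middle, points) and mean local background in fragments (bottom, bars with SE over peaks) for chromosomes 1 to 22 and X. Chromosome X is lowest in each panel, at 1.11 peaks per Mb, a height of 12 and a background of 0.825, and chromosome 15 has the highest background, 1.78.

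On chromosome 1, the local background at GATA6 peaks differed between both sides of its largest peak-free interval, from 121337084 to 145382855. The 370 peaks before it lay at 3.08 per Mb and the 439 peaks after it at 4.30 per Mb, a difference that was not tested. The mean background rose from 1.34 ± 0.0422 to 1.99 ± 0.0494 fragments (SE over peaks), and the exact test gave p = 0.00494, since 4 of the 809 rotations had a difference as large. The test compares the sides and does not place the change at the interval. The last 9 peaks before it, past 120 Mb, had a mean background of 2.14 ± 0.312. In the window from 140 to 160 Mb, just after it, the mean was 1.63 ± 0.126. The median fold was 14.03 before the interval and 11.03 after it, and for the mean fold the exact p was 0.00124. Mean height was 18.7 ± 0.561 before and 23.7 ± 0.682 after, a difference that did not pass the exact test (p = 0.0717). Mean widths, 276 and 286 bp, did not pass it either (exact p = 0.383).

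Chromosome 15 had the highest mean background of all chromosomes, 1.78 ± 0.0708 fragments, and the highest median height, 18. For its background the exact test gave p = 0.087. Only the chromosome farthest from the others can reach 0.0435, and for background that was chromosome X. The p of chromosome 15 therefore only gives its rank, next after chromosome X. Among 141 windows of 20 Mb with at least 20 peaks, the 7 with the highest mean background were all on chromosome 1 or 15. The highest was 2.24 ± 0.123 fragments, on chromosome 1 between 160 and 180 Mb. These regions were singled out after their values were seen.

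**Figure D3:**
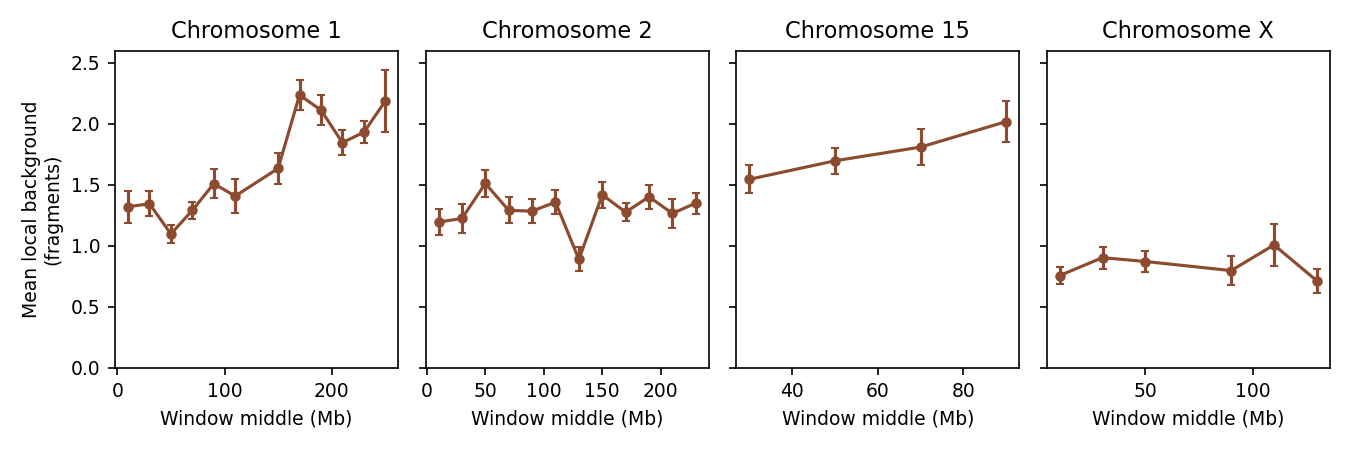
Mean local background at GATA6 peaks in fragments (y axis) in 20 Mb windows along chromosomes 1, 2, 15 and X (x axis, window middle in Mb, hg19), for windows with at least 10 peaks. Points are means with SE over peaks; the chromosome 1 windows reach 2.24 past the peak-free interval, while those of chromosome X stay close to that chromosome's mean of 0.825.

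GATA6 peaks lay closer together than evenly drawn positions. The median distance between neighbouring summits was 128 kb over 7539 pairs, against 260 kb in shuffled lists. Within 10 kb of each other lay 1140 pairs (15.1%), which was 5.70 times the shuffled mean of 200 and above the shuffled maximum of 237. Within 1 kb the excess was 14.1 times, with 282 pairs against a shuffled mean of 19.9. Each count gave a permutation p of 0.001, the smallest that 1000 shuffles can give. The shuffles also drew positions inside peak-free intervals, such as the 32.7 Mb on chromosome 9, which by itself sets shuffled positions farther apart. These distances were not compared with shuffles within 1 Mb bins, so the size of the excess is partly set by such intervals.

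**Figure D4:**
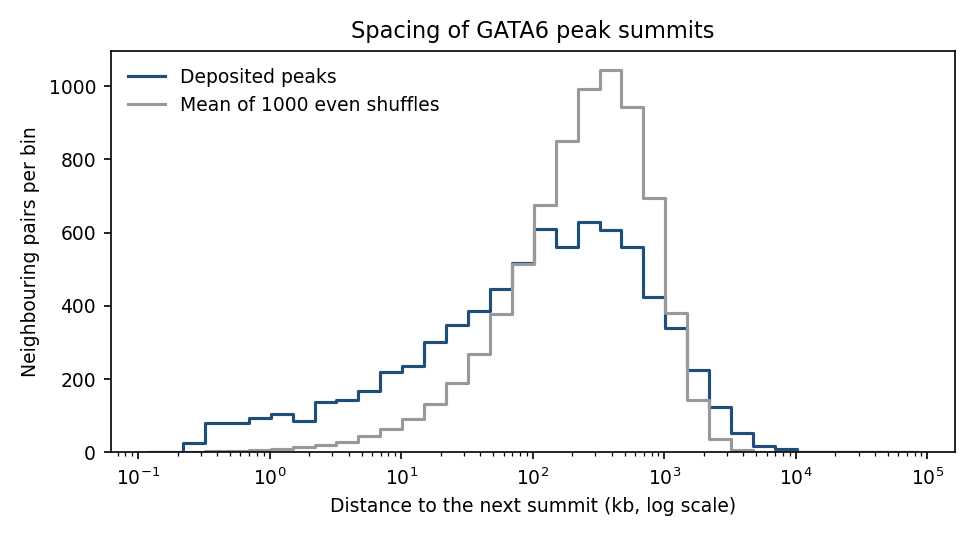
Number of neighbouring GATA6 summit pairs per bin (y axis) by their distance in kb (x axis, log scale) for the deposited peaks and for the mean of 1000 even shuffles. The deposited list exceeds the shuffles at short distances, with 1140 pairs within 10 kb against a shuffled mean of 200.

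Of the 7562 peaks, 5504 were alone and 2058 had a neighbour within 10 kb. They formed 35 clusters of 4 or more peaks, against a shuffled mean of 0.153 and a maximum of 3 (permutation p = 0.001, the smallest possible). The largest held 7 peaks on chromosome 12 from 71546627 to 71561043, with heights from 11 to 45. A cluster of 6 peaks lay on chromosome 8 from 110592397 to 110623754, with heights from 12 to 21. Among 5 clusters of 5 peaks were those on chromosome 14 from 55583153 to 55594677 and on chromosome 8 from 37447917 to 37456372. The highest peak within any cluster, 87 fragments, lay in one of 4 peaks on chromosome 1 from 207115092 to 207129086. When summits within 1 kb were joined first, 15 clusters were counted, and the better-scoring part of the list held 3.

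At a wider scale, the densest 1 Mb bins were chromosome 8 from 128 to 129 Mb and chromosome 17 from 63 to 64 Mb, with 23 peaks each. Chromosome 8 from 8 to 9 Mb followed with 19. In shuffled lists no bin held more than 15 peaks, and 10 bins exceeded that number. The shuffles also placed peaks inside peak-free intervals, which lowers their counts elsewhere. Of the 12 densest bins, those on chromosome 1 lay from 72 to 73, 168 to 169, 185 to 186 and 233 to 234 Mb. Mean local background was 1.28 fragments in the bin on chromosome 8 from 37 to 38 Mb. In the rest of the 12 it ran from 1.53 to 2.98, above the mean of 1.37 over autosomal peaks. Whether raised control signal contributed to these bins was not tested.

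Peaks with a neighbour within 10 kb were slightly higher than peaks alone, with medians of 17 and 15 fragments. They were wider, at 262 and 248 bp, and their local background was higher, at 1.22 and 0.998 fragments, while their median fold was lower, at 13.03 and 14.32. Each of these 4 differences gave p = 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 1.2e-05 over 5 tests. The permutations relabelled single peaks, whereas peaks with a neighbour come in linked groups and are not independent, so these p-values are too small. The −log10 p, with medians of 13.21 and 12.83, gave a permutation p of 0.574. With a linking distance of 5 kb the difference in height was 1 fragment and did not pass the permutation test (p = 0.288).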

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

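For the peaks outside chromosomes 1 to 22 and X no test was made. The low-background test of gathering, both tests of the background floor and the test of DNA copies were chosen after the values had been seen, as were the stricter thresholds and the look at floor heights in the thinning of autosomal peaks.

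The list held 6 peaks that entered no comparison because they lay outside chromosomes 1 to 22 and X. On unplaced or unlocalised contigs, 5 peaks had heights of 55, 30, 29, 11 and 8 fragments. The highest of them, with a fold of 13.7, lay on a contig assigned to chromosome 7, and the peak of height 30, on an unplaced contig, had a local background of 5.99. The remaining peak, of height 11, lay on chromosome Y from 59019658 to 59020100.

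Peaks gathered closer together than evenly spread positions, with 35 clusters. Splitting of single wide regions was argued against as the whole cause, since 15 clusters were left after summits within 1 kb were joined, against at most 2 in shuffles. Uneven density over 1 Mb bins was argued against likewise, since the 35 clusters exceeded the maximum of 7 when each bin kept its number of peaks. The local background of peaks with a neighbour was higher by 0.224 fragments (95% bootstrap interval 0.120 to 0.224). Among peaks at or below the median background, 22 clusters of at least 3 peaks formed, against at most 6 in shuffles and 177 in the whole list. Gathering was thus not confined to peaks above the median background. That median, 1.05, lies above the floor of 0.489, so these peaks can still have raised background, and raised background as the only cause was not excluded. Gathering of binding sites within regulatory regions may also contribute. No biological explanation was tested, since hg19 sequence, annotation and the histone modification libraries were not used here.

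The local background at peaks lay above its floor, with a median of 1.05 fragments. An even control at the floor's depth, read through the same windows, gave a median of 0.698 in all 1000 simulations. A small number of repeated or multiplied regions was argued against as the whole cause, since even the lower quartile of all peaks, 0.873 (95% bootstrap interval 0.838 to 0.873), lay above that median. An even control 1.81 times as deep as the floor could give the mean background of the autosomes other than 1 and 15. Nothing but the mean was matched, and 6.04% of the peaks on these autosomes had the floor background. That share was not simulated, but an even control of that depth would seldom give the floor, so it alone falls short. A floor set too low as part of the cause stays open, as does an open chromatin bias of the control. Neither was tested, and no biological explanation was tested.

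Chromosomes differed in peaks per Mb, and no biological explanation was tested here. Gap sequence in the spans was argued against as the whole cause by a permutation of the occupied bins (p = 0.0002), but the autosomes alone gave p = 0.134. Peaks per Mb rose with mean background over 23 chromosomes (rho = 0.47, permutation p = 0.0227), with a 95% bootstrap interval of 0.022 to 0.80 for rho. Pearson r was 0.64 (permutation p = 0.002). Without chromosomes 17 and X, rho was 0.52 (permutation p = 0.0158) and r was 0.54. Chromosome 17 ranked 1 in density but 18 in background, while chromosome X was lowest in both. Without chromosomes 1, 15 and X, rho was 0.25 (permutation p = 0.284). Both sets were chosen after the values were seen. Fewer reads from chromosome X stay open: with 1 of 2 fragments kept, 81.5% of autosomal peaks stayed above the lowest deposited −log10 p, above the 41.4% (95% interval 29.1 to 53.7) that chromosome X showed, which met the result set in advance as evidence against this cause. The lowest −log10 p, 4.34, did not describe entry into the list, since a height of 5 at the floor background gives 4.90 but 0 of 469 peaks at the floor had it. At the 5th percentile the kept share, 59.2%, was still above that interval. At the 10th and 25th it was 51.7% and 46.6%. Chromosome X stood at 41.2%, 39.8% and 40.3% at the same percentiles. These percentiles do not describe entry either, since 15 floor peaks of height 6 had a −log10 p of 6.06, under the 5th percentile of 6.69. Kept autosomal peaks had a median height of 9 at the lowest threshold, against 12 on chromosome X. At the 5th, 10th and 25th percentiles it was 11, 12 and 13.7, against 12, 13 and 14.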

How the results depend on the processing

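Of 84 alternatives, 22 were fixed before the data were examined and 62 were chosen afterwards. Of these, 57 left the result on its side of the threshold or within its range, and 1 reversed a direction: without its largest peak-free interval, chromosome 9 went from 0.843 to 1.03 times the expected number of peaks and lost its call (exact binomial test, adjusted p = 0.708), since the span shrank. Of the others, 10 moved a value, 13 ended a call and 3 gained one. The better-scoring part of the list held 3785 peaks by construction. Over occupied 1 Mb bins, which shrink density differences by construction, 2 chromosomes were off an even spread in place of 9. Without peaks that had a neighbour, the mean background of chromosome X differed from the autosomes by −0.494 fragments in place of −0.546. That of chromosome 15 was 0.466 above the other chromosomes in place of 0.493. Their ranks in the exact test changed places (exact p = 0.087 for chromosome X and 0.0435 for chromosome 15). Only the chromosome farthest from the others can pass this test, so the lost and the gained call are a swap of ranks and not separate results. On chromosome 1 the difference in mean height was 6.62 fragments in the better-scoring part and passed the test (exact p = 0.0122), but a filter on −log10 p asks for greater heights where the background is higher, as it is after the interval. Clusters numbered 12 with linking within 5 kb, 105 within 20 kb, 177 for at least 3 peaks, 2 for at least 6, 3 in the better-scoring part and 15 with summits within 1 kb joined, each above every shuffle; the definitions of distance, size and list set these counts. The height difference of peaks with a neighbour was 1 fragment at 5 kb (permutation p = 0.288). For the others the cause was not tested. Whole chromosome lengths, leaving out each GATA6 replicate, and the alternatives for promoters, motifs and gene lists were not run, since no genome of this build and no peaks per library were used here. No paired analysis was possible because the list carries no values per library. Heights of a few fragments limit single peaks.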

Other observations

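The test of DNA copies and the neighbouring heights were chosen after the data had been seen. Neighbouring GATA6 peaks resembled each other little in height. Over 1140 pairs within 10 kb, Spearman's rho of the heights was 0.079 (permutation p = 0.0071, adjusted p = 0.0213 over 3 distance ranges), over 2235 pairs 10 to 100 kb apart it was 0.049 (permutation p = 0.0235, adjusted p = 0.035), and over 4164 pairs more than 100 kb apart it was 0.021 (permutation p = 0.167). The spread of heights differed between clusters, with no comparison against random groups of peaks. On chromosome 9 from 19192418 to 19202655, 4 peaks had heights from 10 to 71, while on chromosome 5 from 157341569 to 157357972, 4 peaks had heights from 7 to 13.

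The highest local background of the list, 8.99 fragments, lay under a peak of height 31 on chromosome 15 from 67062957 to 67063168, where the fold was 3.45. On chromosome 1, the bin from 168 to 169 Mb had the highest median height of the 12 densest bins, 33 fragments, with a mean background of 2.98.

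The local background may follow the number of DNA copies in LS174T cells, which is a hypothesis from these data alone. The depth of an even control that would give the mean background, relative to the autosomes other than 1 and 15, was 0.528 for chromosome X (95% bootstrap interval 0.444 to 0.606). It was 1.02 (0.939 to 1.10) for chromosome 1 before its peak-free interval, 1.61 (1.52 to 1.71) after it, and 1.42 (1.30 to 1.56) for chromosome 15. The interval for chromosome X holds the ratio of 1 copy to 2, and that for chromosome 15 the ratio of 3 copies to 2, but these comparisons were set when the backgrounds were known, so they decide nothing. For chromosome 1 after its peak-free interval, the ratio of 3 copies to 2 lies outside. The autosomes of the reference also differed among themselves. Their mean background ran from 1.10 on chromosome 19 to 1.39 on chromosome 3, against 1.32 for the reference as a whole. No ratio was computed for single autosomes of the reference. The control behind the background is not named, and the even profile was assumed and matched by the mean only. Copy number was not measured, so the hypothesis stays open.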
